A study of Mus musculus with 9 samples.

How the data were processed

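RNA of sorted mouse cells was hybridized to Affymetrix arrays in 3 groups of 3 samples, control, abnormal non-malignant and NIC tumor, 1 array per sample. Per the labels, RNA was taken with TRIZOL and RNeasy, amplified to biotin-labelled cRNA and processed in a standard way by a microarray core. The deposited table holds log2 values of 45101 probe sets, normalized between arrays by the authors; the method of background correction, normalization and summarization is not stated. The base of the logarithm was read from the values, which run from 2.68 to 14.57. The series also names array CGH and spectral karyotyping, which were not used here. The labels do not say which cells were sorted or whether the samples came from separate animals. They also do not say that the replicate numbers pair the samples.

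Of the probe sets, 64 are Affymetrix controls, 34945 carry 1 gene symbol, 932 carry several and 9160 none. Only those with 1 symbol were assigned to genes, 34741 of them by Entrez ID, 143 by symbol and 61 under the name in the platform annotation, which gave 18193 genes. Each gene was represented by its probe set with the highest mean log2 value over the 9 arrays. A gene was tested if this probe set lay above the 40th percentile of the array on at least 3 arrays, which left 13296 genes. The array medians of the 23369 probe sets that passed this filter differed by at most 0.25, under the limit of 0.3 set for further normalization, so none was added. As these are arrays, their number limits the precision.

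The tables were read in Python 3.11.15 with pandas 2.3.3 and the models fitted in R 4.3.3 with limma 3.58.1. A linear model with 1 mean per group was fitted to all 9 arrays (residual degrees of freedom 6, prior degrees of freedom 3.6), with moderated variances that follow a trend on the mean level. Each pair of groups was compared, two-sided. A gene was called when its Benjamini-Hochberg adjusted p over all genes tested was under 0.05. Non-overlap means that all 3 values of a group lie beyond all 3 of the other; an exact permutation test of 3 against 3 cannot give a p under 0.1. The fit was tested on simulated data with 200 changed genes in each of 5 draws. It recovered 60.2% of 2-fold and 95.4% of 4-fold changes at the spread of tumors and controls, with 34.2 false calls per draw, and 58.6% and 94.4% at the spread of non-malignant samples and controls, with 0.2 false calls. Beside at most 200 true calls, 34.2 false ones are a larger share than the threshold of 0.05 allows. The adjusted p was thus too liberal for tumors against controls in this simulation. Tumors against non-malignant samples were not simulated. The simulated arrays were independent of one another and did not model non-malignant arrays 2 and 3, which lay close together. The 0.2 false calls may therefore not hold for the real non-malignant samples.

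A set of 30 gene lists with 430 entries was written down, of which 397 entries matched a gene with a probe set of its own; the rest were not analysed here. The lists cover Notch target genes, Myc target genes, ribosome biogenesis, p53 target genes, E proteins with Id proteins and partners, CD4+CD8+ thymocyte, early thymocyte progenitor, mature T cell, B cell, myeloid, antigen-presenting cell, erythroid and thymic stroma markers, TCR and CD3 signalling, cytotoxic and NK genes, G2/M and mitosis, G1/S and DNA replication, glycolysis, oxidative phosphorylation, interferon response, MHC class I presentation, immediate early genes, heat shock, the unfolded protein and amino acid stress response, the BCL2 family, NF-kappaB response, T-ALL driver genes, housekeeping genes, sex-linked genes and study genes. For 27 of them a set test was run with camera at a preset correlation of 0.01, adjusted over the 81 tests of 27 lists and 3 comparisons; camera with an estimated correlation and fry were run beside it. The last 3 lists received counts and values only. Calls were also counted with the adjustment over the list alone.

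The genes named are, in each comparison, the 8 called genes with the largest rise and the 8 with the largest fall whose groups do not overlap (without clone and predicted names), the 3 members of each list with the smallest adjusted p, and all study genes. Other genes, such as Igf1r and Lyz2, and Tap2 in tumors against controls, were chosen after their values were seen. The model, filter, lists, naming rule and 23 of the 27 alternative settings were fixed before the data were examined. These alternatives were quantile and median scaling, no filter and a filter at the 60th percentile, all probe sets or their mean per gene, other variance models and array weights, only the 2 groups compared, the replicate number as a block, stricter thresholds, an estimated correlation, and leaving out each array, where the probe set of each gene was chosen again. A floor on low values had been planned for a linear table and was not run on this one. The alternatives added after seeing the data were non-malignant arrays 2 and 3 averaged as 1, the mean signal of the hybridization spikes or of the B1 repeat probe set as a covariate, and array weights per group. Also added then were bounds on the changes of dim genes among those named and called, for which values of the dimmer group under the 40th percentile of their array were set to that percentile.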

Results

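Expression was measured on 9 mouse arrays, 3 in each of the groups control, abnormal non-malignant and NIC tumor, in a series on T cell acute lymphoblastic leukemia (T-ALL) and on what excess NOTCH1 does short of malignancy. NOTCH1 is a receptor that drives T lineage commitment and is often mutated in T-ALL. Each array gave log2 values for 45101 Affymetrix probe sets from sorted cells. The labels spell out neither NIC nor the sorted population, and do not say whether the samples came from separate animals, so the p-values speak only to the spread between these samples. Array medians lay between 5.67 and 5.77, and the number of arrays limits the precision. The root mean square SD of a gene within a group was 0.27 in controls, 0.23 in non-malignant samples and 0.49 in tumors.

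Several arrays differed from the rest of their group. Non-malignant arrays 2 and 3 were the closest pair of all, with an SD of 0.16 for the differences between their genes and 0 genes 2-fold apart. The next closest pair, controls 1 and 3, had an SD of 0.3 and 121 such genes. The counts are therefore also given with non-malignant arrays 2 and 3 averaged and counted as 1, an alternative chosen after seeing the data. Tumor array 1 lay closer to the non-malignant arrays (SD of the differences 0.46 to 0.47) than to tumor arrays 2 and 3 (0.63 and 0.79). Tumor array 3 had the narrowest spread of values (SD 1.97, against 2.12 to 2.19 on the others) and the highest bioB spike-in signal (10.67, against 7.22 to 9.05). Control array 2 alone carried signal of the Y-linked genes Eif2s3y (8.69, at most 4.18 elsewhere) and Kdm5d (7.37, at most 4.13 elsewhere), and had the lowest Xist (10.27, at least 12.38 elsewhere). The signal of the B1 repeat probe set split the arrays in another way, with 11.3 to 12.16 on control 1, non-malignant 1 and the 3 tumors and 10.31 to 10.98 on the other 4. The arrays numbered 1 scored 30.7, 27.1 and 40.5 on the fourth principal component (8.3% of the variance), against −28.3 to 4.4 on the others. Whether arrays of the same number were processed together is not stated, and the main fit does not model it. With the replicate number as a block, tumors against controls gave 1915 genes, non-malignant samples against controls 399 and tumors against non-malignant samples 287.

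The comparison of abnormal non-malignant samples with controls addresses the non-malignant side of NOTCH1 excess. Most of the measured Notch target genes rose in the abnormal non-malignant samples. Dtx1, which encodes a ubiquitin ligase of the Notch pathway, rose from 8.04 ± 0.06 in controls to 13.21 ± 0.07 (log2, mean ± SD, n = 3 each). Il2ra, which encodes the IL-2 receptor chain CD25, rose from 5.06 ± 0.27 to 10.11 ± 0.24, and the transcriptional repressors Heyl and Hes1 rose by 5.98 and 3.81. Of the 12 measured Notch target genes, 8 rose, Igf1r fell and 3 did not pass (adjusted over the list alone, 9 rose and 1 fell). The call of Igf1r ended without control 1, control 2 or any 1 non-malignant array. The list as a whole was higher (median log2 fold change 3.07, camera adjusted p = 3.09e-11, and adjusted p = 0.0833 with an estimated correlation). Notch1 itself stood at 12.91 ± 0.06 against 10.05 ± 0.27 in controls, with every non-malignant array above every control. It did not pass in the fit of all 3 groups (log2 fold change 2.86, adjusted p = 0.0802), whose residual spread includes that of Notch1 in the tumors (SD 1.96). It passed without tumor array 1 or tumor array 2, and its log2 fold change stayed between 2.74 and 3 with any 1 array left out.

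**Figure D1:**
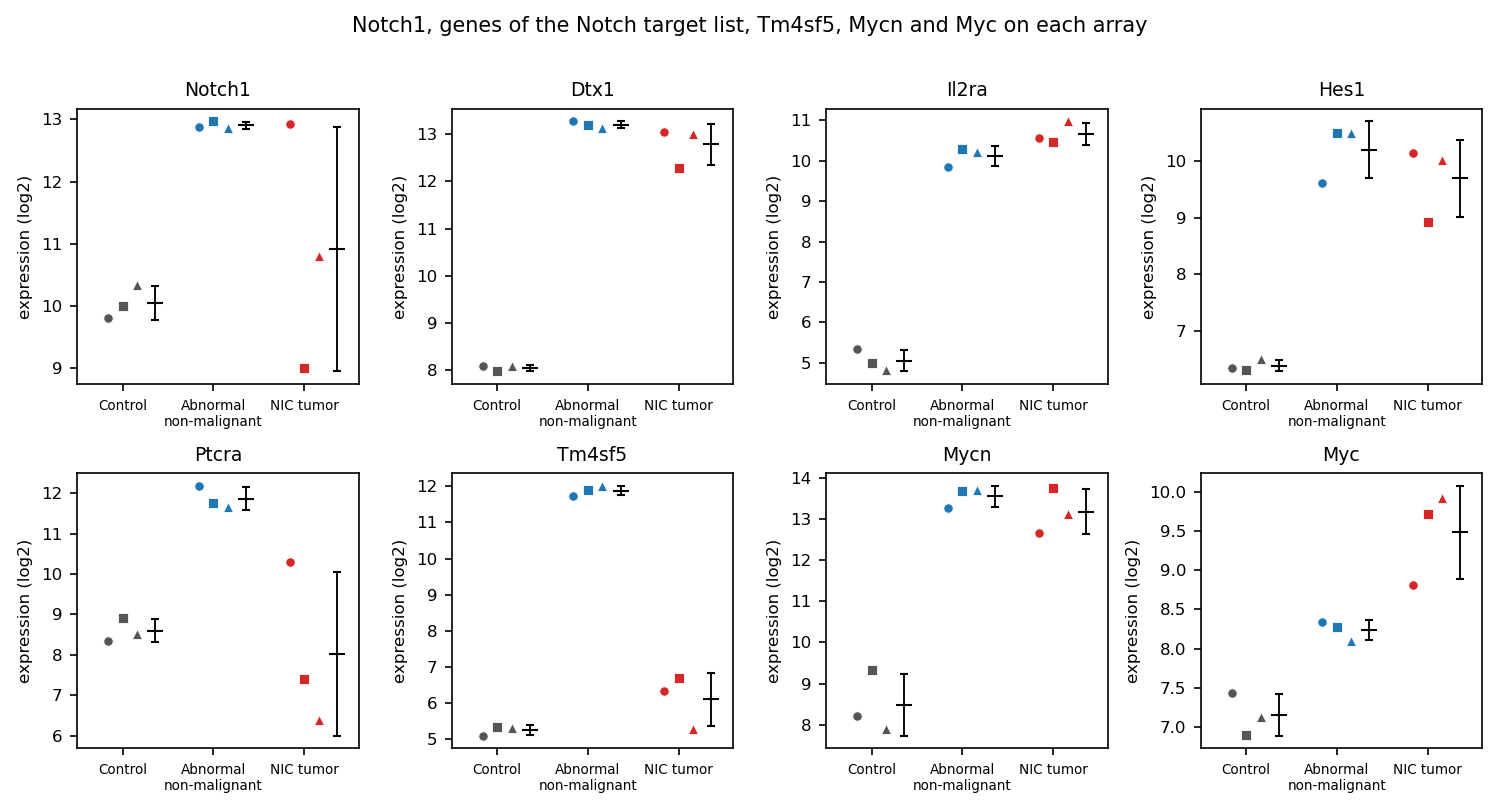
Expression on the log2 scale of Notch1, 4 genes of the Notch target list (Dtx1, Il2ra, Hes1, Ptcra), Tm4sf5, Mycn and Myc on each array; circles, squares and triangles are arrays 1, 2 and 3 of a group, and the black bars give the mean ± SD of the 3. Dtx1 lies near 8.04 in controls and 13.21 in non-malignant samples, while Notch1 in the tumors spans 9 to 12.92.

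Interferon response genes and antigen presentation genes were higher in the non-malignant samples as well. Of 12 measured interferon response genes, 7 rose and none fell (10 rose when adjusted over the list alone), with a median log2 fold change of 1.9 (camera adjusted p = 4.91e-12, and adjusted p = 0.0833 with an estimated correlation). Ifit1, an antiviral RNA-binding protein, rose by 3.65 ± 0.39 (SE; at least 3.17 with 2 of 3 controls under the 40th percentile of the array set to that level), Irf7, a transcription factor of the type I interferon response, by 2.13 ± 0.26, and Oas1a by 1.93 ± 0.24. Of 9 MHC class I presentation genes, 5 rose and none fell (8 rose when adjusted over the list alone; camera adjusted p = 6.59e-09, and adjusted p = 0.0753 with an estimated correlation). Among them were the light chain B2m (1.86), the peptide-loading factor Tapbp (1.19) and the heavy chain H2-K1 (1.29). Of this list 3 rose without control 1, non-malignant 2 or non-malignant 3. Markers of myeloid cells moved with these genes: 1 of 15, Ctss, rose (2.34, between 2.02 and 2.68 with 1 array left out, its call ending without control 3, non-malignant 2 or non-malignant 3), and 3 rose when adjusted over the list alone (camera adjusted p = 0.00776, and adjusted p = 0.458 with an estimated correlation). The granulocyte genes S100a8 and S100a9 stood higher without passing (2.76, adjusted p = 0.0837, and 2.61, adjusted p = 0.117). Ngp (0.99), Ltf (0.68), Mpo (0.34) and Camp (0.29) did so as well, whereas Lyz2, abundant in myeloid cells, differed by 0.07 and Elane by 0.05. Of the 6 antigen-presenting cell markers, 0 passed by limma, also at an unadjusted p under 0.05.

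Cytotoxic and mature T cell genes rose too. Of 10 cytotoxic and NK genes, 5 rose and none fell (the same count adjusted over the list alone; camera adjusted p = 1.93e-05, and adjusted p = 0.0753 with an estimated correlation). Perforin, Prf1, rose by 3.8 ± 0.34 (SE), Cst7 by 1.96 and Nkg7 by 1.3. Of 14 mature T cell markers, 4 rose and none fell (6 rose when adjusted over the list alone; camera adjusted p = 3.68e-06, and adjusted p = 0.0753 with an estimated correlation). Among them were Klf2 (2.76), a regulator of T cell trafficking, Gimap4 (2.31) and the integrin Itgb7 (1.89). The 8 largest rises, with log2 fold changes from 5.05 to 8.66, were those of Dsp (8.66), which encodes the desmosome protein desmoplakin, Tm4sf5 (6.63), Epas1 (6.25), which encodes the hypoxia factor HIF-2alpha, Heyl, Dtx1, Nln (5.15), Mycn (5.09) and Il2ra. Dsp and Epas1 lay under the 40th percentile of the array on all 3 controls, where the table does not tell signal from background, so their sizes and order are uncertain. Set against that level, they rose by at least 7.02 and 5.32. Among the 8 largest falls were Bex1 (−4.06), the cholesterol exporter Abca1 (−3), Afap1 (−2.84), Dhrs3 (−2.78), an enzyme of retinoid metabolism, Plxdc1 (−2.59) and Tdrp (−2.54). The other 2, Dgkeos (−3.41) and Map4k5 (−2.64), lost the call without non-malignant array 2 or 3, and Map4k5 also without any other control or non-malignant array. With 1 array left out their log2 fold changes lay between −3.82 and −2.81 and between −2.93 and −2.37. Bex1 and Map4k5 lay under that percentile on all 3 non-malignant arrays, so that they fell by at least 3.64 and 2.25, and Afap1 on 2 of them (at least 2.31). Without any 1 control Bex1 did not pass the filter on dim probe sets and was not tested; it kept the call in the other 6 fits.

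Growth and differentiation lists shifted with few or no single genes passing. Myc target genes were higher as a list (median 0.54, camera adjusted p = 8.58e-06, and adjusted p = 0.303 with an estimated correlation). Of its 17 genes 1 was called, Ldha (0.5, between 0.46 and 0.55 with 1 array left out, its call ending without any 1 control, any 1 non-malignant array or tumor 2), and 12 adjusted over the list alone. Myc itself had a log2 fold change of 1.09 (adjusted p = 0.0805). Ribosome biogenesis genes were higher as a list with 0 of 21 called by limma (8 at an unadjusted p under 0.05, 3 adjusted over the list alone; camera adjusted p = 3.36e-05, and adjusted p = 0.38 with an estimated correlation). Glycolysis genes were higher with 3 of 12 called (5 adjusted over the list alone; camera adjusted p = 0.0004, and adjusted p = 0.235 with an estimated correlation). These were Ldha, Slc2a3 (1.89) and Pgam1 (0.95), whose calls ended without control 1, non-malignant 2 or non-malignant 3. The call of Slc2a3 (1.79 to 1.99 over the 9 fits) also ended without control 3 or non-malignant 1, and that of Pgam1 (0.76 to 1.08) without control 2. Early thymocyte progenitor markers had a median of 0.08 and a mean of 0.74 (camera adjusted p = 0.0107, and adjusted p = 0.34 with an estimated correlation), the largest value being that of Il2ra (5.05), which is also on the Notch target list. Mpzl2 stood 2.38 higher without passing. Its other probe set, which had the highest mean without any 1 control, tumor 2 or tumor 3, gave 5.04 to 5.78 there. Besides Il2ra, 1 of the 13 was called, Lyl1 (0.87, between 0.81 and 0.97 with 1 array left out, its call ending without any 1 control or non-malignant array), and 4 in all adjusted over the list alone. Markers of CD4+CD8+ thymocytes were lower as a list with 0 of 11 called (3 lower at an unadjusted p under 0.05 and adjusted over the list alone; camera adjusted p = 0.00188, and adjusted p = 0.38 with an estimated correlation). G2/M and mitosis genes were lower with 0 of 19 called (2 at an unadjusted p under 0.05; camera adjusted p = 0.000539, and adjusted p = 0.484 with an estimated correlation). Control 2, with a list median of −0.49 relative to the mean of the controls, lay below all 3 non-malignant arrays (−0.34 to −0.22), and controls 1 and 3 at 0.18 and 0.33 above them. The median log2 fold change ran from −0.48 without control 2 to −0.16 without control 3 with 1 array left out, and the list was called in all 9 fits. Oxidative phosphorylation genes were higher with 0 of 19 called (5 at an unadjusted p under 0.05; camera adjusted p = 0.0327, and adjusted p = 0.354 with an estimated correlation). Its call ended without control 2, non-malignant 2, tumor 1 or tumor 2.

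The remaining lists did not pass by camera in the non-malignant samples. By fry the NF-kappaB response, T-ALL driver and E protein lists passed (adjusted p = 0.0125, 0.0304 and 0.0388). Id1, an inhibitor of E proteins, rose by 3.74 ± 0.36 (SE), and with Lyl1 it made 2 of 8 called among E proteins, Id proteins and partners (2 adjusted over the list alone). Single genes rose in the lists of B cell markers (Cd22, 1.99, 1 of 10), NF-kappaB response (Bcl3, 1.83, 1 of 10), T-ALL driver genes (Lyl1, 1 of 17), housekeeping genes (B2m, 1 of 8) and TCR and CD3 signalling genes (Zap70, 0.64, 1 of 13, between 0.57 and 0.7 with 1 array left out, its call ending without any 1 control or non-malignant array). Adjusted over the list alone, 1 rose and 1 fell among both the B cell markers and the NF-kappaB response genes, 1 of the T-ALL driver genes rose, and 2 each of the housekeeping and the TCR and CD3 signalling genes rose. The B cell list had a median of 0.04 and a mean of 0.05 while its test pointed down, as did that of the BCL2 family with a median of 0.08 and a mean of 0. By limma, 0 of 16 p53 target genes passed (4 at an unadjusted p under 0.05), 0 of 7 erythroid markers (2), 0 of 8 thymic stroma markers (0), 0 of 18 G1/S genes (1), 0 of 12 immediate early genes (2), 0 of 8 heat shock genes (2), 0 of 12 genes of the unfolded protein and amino acid stress response (1) and 0 of 11 BCL2 family genes (2). Adjusted over the list alone, 1 immediate early and 1 heat shock gene rose. Of 16 study genes, Hes1 and Dtx1 rose (5 rose when adjusted over the list alone; median −0.19, mean 0.77), and the pre-TCR chain gene Ptcra stood 3.27 higher (adjusted p = 0.0558). The others that did not pass were Rag1 (−0.69), Rag2 (−0.22), Cd4 (−0.43), Cd8a (−0.36), Cd8b1 (−0.58), Cdkn2b (−0.16), Mdm2 (−0.43), Mdm4 (−0.41), Tcf3 (−0.07), Tcf12 (0.26) and Id3 (−0.71). Xist, the 1 sex-linked gene above the filter, had log2 fold changes of 0.62 here, 0.63 in the tumors against controls and 0.01 between tumors and non-malignant samples, and did not pass.

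In all, limma called 469 of 13296 genes between non-malignant samples and controls, 382 higher and 87 lower (301 and 67 of them at least 2-fold), against 1766 at an unadjusted p under 0.05. The groups did not overlap in 26.1% of all genes, nor in any of the 469. Chance gives 10% for independent samples, and more if non-malignant arrays 2 and 3 are 1 sample. The count of called genes was 206 with non-malignant arrays 2 and 3 averaged, 203 without array 2 and 218 without array 3, and it was 287, 304 and 280 without control 1, 2 or 3 and 709 without tumor 1. With only these 2 groups in the fit it was 1119.

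The comparison of NIC tumors with controls addresses expression in the malignant state. Part of the Notch target list rose in the tumors, alongside Myc and the machinery of growth. Il2ra rose from 5.06 ± 0.27 to 10.66 ± 0.27 (log2, mean ± SD, n = 3 each) and Dtx1 from 8.04 ± 0.06 to 12.79 ± 0.44. Heyl and Hes1 rose by 4.62 and 3.31. Of 12 Notch target genes, 6 rose and 2, Igf1r and Gata3, fell (the same counts adjusted over the list alone; camera adjusted p = 0.00179, and adjusted p = 0.314 with an estimated correlation). Gata3 (−1.28) lost its call without any 1 control or non-malignant array, at −1.57 to −0.82. Notch1 differed widely between the tumors, at 12.92, 9 and 10.81 on arrays 1, 2 and 3, so that its log2 fold change of 0.86 did not pass (adjusted p = 0.448) and was −0.14 without tumor 1. The second Notch1 probe set gave 12.13, 9.57 and 11.09 on the same arrays, against 9.14 to 9.53 in controls.

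Myc, which drives cell growth, rose from 7.15 ± 0.27 to 9.49 ± 0.6 (log2 fold change 2.34, adjusted p = 0.00133). Of 17 Myc target genes, 11 rose and none fell (12 rose when adjusted over the list alone; camera adjusted p = 5.34e-07, and adjusted p = 0.267 with an estimated correlation). Examples were Srm, the spermidine synthase, at 2.55 ± 0.33 (SE) and Cad, which starts pyrimidine synthesis, at 2.38. Of 21 ribosome biogenesis genes, 18 rose and none fell (19 rose when adjusted over the list alone; camera adjusted p = 2.03e-10, and adjusted p = 0.271 with an estimated correlation). Examples were Mybbp1a at 2.35, Rrp12 at 2.14 and Pes1 at 1.52. Of 12 glycolysis genes, 8 rose and none fell (10 rose when adjusted over the list alone; camera adjusted p = 1.06e-05, and adjusted p = 0.167 with an estimated correlation). Examples were Aldoa at 1.83, Pkm at 1.39 and Ldha at 0.97. Of 19 oxidative phosphorylation genes, 5 rose and none fell (8 rose when adjusted over the list alone; camera adjusted p = 0.000178, and adjusted p = 0.201 with an estimated correlation). The changes there were small, with Cox5b at 0.53, Ndufv1 at 0.75 and Cox6c at 0.32, and each lost its call without any 1 control, tumor 2 or tumor 3, the latter 2 genes also without non-malignant 2 or 3, at log2 fold changes of 0.45 to 0.6, 0.58 to 0.83 and 0.29 to 0.34 with 1 array left out. Cell division genes did not rise with them. Of 19 G2/M and mitosis genes, 6 fell and none rose (8 fell when adjusted over the list alone; camera adjusted p = 7.73e-05, and adjusted p = 0.434 with an estimated correlation). Examples were Top2a at −0.95, Cenpe at −1.13 and Mki67 at −0.93. On control 2 the list median (−0.49) lay within the range of the tumors (−0.51 to −0.39), while controls 1 and 3 stood at 0.18 and 0.33. The median log2 fold change of −0.41 ran from −0.74 without control 2 to −0.22 without control 3 with 1 array left out, with 3 to 6 genes called, and the list was called in all 9 fits. Of 18 G1/S and DNA replication genes, Mcm3 rose (1.33) and 4 fell, among them Ccne2 (−2.48, at least 1.74 lower with the 2 tumor arrays under the 40th percentile set to it) and Rrm2 (−0.96), with the same counts adjusted over the list alone and no shift of the list (camera adjusted p = 0.323). The number of ribosome biogenesis genes that rose was 11 without control 2 or tumor 2, that of glycolysis genes 5 without control 1 or 2, and that of oxidative phosphorylation genes 0 without any 1 control or tumor 2 and 1 without non-malignant 2, non-malignant 3 or tumor 3. Of the G1/S genes 2 fell without control 1, control 3 or tumor 2.

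Markers of CD4+CD8+ thymocytes were lower in the tumors. Of 11 measured, 8 fell and none rose (10 fell when adjusted over the list alone; camera adjusted p = 5.68e-08, and adjusted p = 0.235 with an estimated correlation). The recombination genes Rag1 and Rag2 fell by 4.4 and 3.27 on the log2 scale, the chemokine receptor gene Ccr9 fell by 4.7 and Arpp21 fell by 1.95. With the spike-in signal as a covariate Rag1 and Ccr9 were not called, while Rag2 and Arpp21 were. That signal was higher on every tumor than on all other arrays, so the lost calls do not tell an artifact from a group difference. On the tumor arrays 1, 2 and 3 the median of these markers lay at −1.15, −1.86 and −2.9 relative to the controls, so that the size of the change differed between tumors. Of 13 TCR and CD3 signalling genes, 5 fell and 1 rose (6 and 2 adjusted over the list alone; camera adjusted p = 0.0065, and adjusted p = 0.432 with an estimated correlation). Rasgrp1 fell by 2.29, Cd247, the CD3 zeta chain, fell by 2.09 and the kinase Fyn rose by 2.01. The call of this list ended without tumor 2. Of the 14 mature T cell markers, 4 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.147), with Gimap4 at 3.24, S1pr1, which guides T cell exit from lymphoid organs, at 2.84 and Klf2 at 2.71. Of 10 cytotoxic and NK genes, 4 rose (4 adjusted over the list alone; camera adjusted p = 0.192), with Prf1 at 2.28 and Cst7 at 1.26, and Il2rb at 1.72 (1.31 to 2.19 with 1 array left out, its call ending without control 2 or 3). Of 9 MHC class I presentation genes, 7 rose, with H2-K1 at 1.51, and Tap2 fell (the same counts adjusted over the list alone; camera adjusted p = 0.0043, and adjusted p = 0.243 with an estimated correlation). The list call did not hold without tumor 1. No interferon response gene passed by limma (0 of 12, 1 higher and 1 lower at an unadjusted p under 0.05), and the median of that list was 0.16 while its mean was −0.06. Without any 1 control 5 of the CD4+CD8+ thymocyte markers fell. Of the TCR and CD3 signalling genes 3 fell without control 1, control 2, tumor 2 or tumor 3, and 9 without tumor 1. Of the mature T cell markers 1 fell without control 1, control 3 or tumor 2. Of the cytotoxic and NK genes 2 rose without control 2 or 3. Of the MHC class I presentation genes 2 rose without control 3 and 4 without control 1, and 0 fell without any 1 array other than non-malignant 1 and tumor 1.

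**Figure D2:**
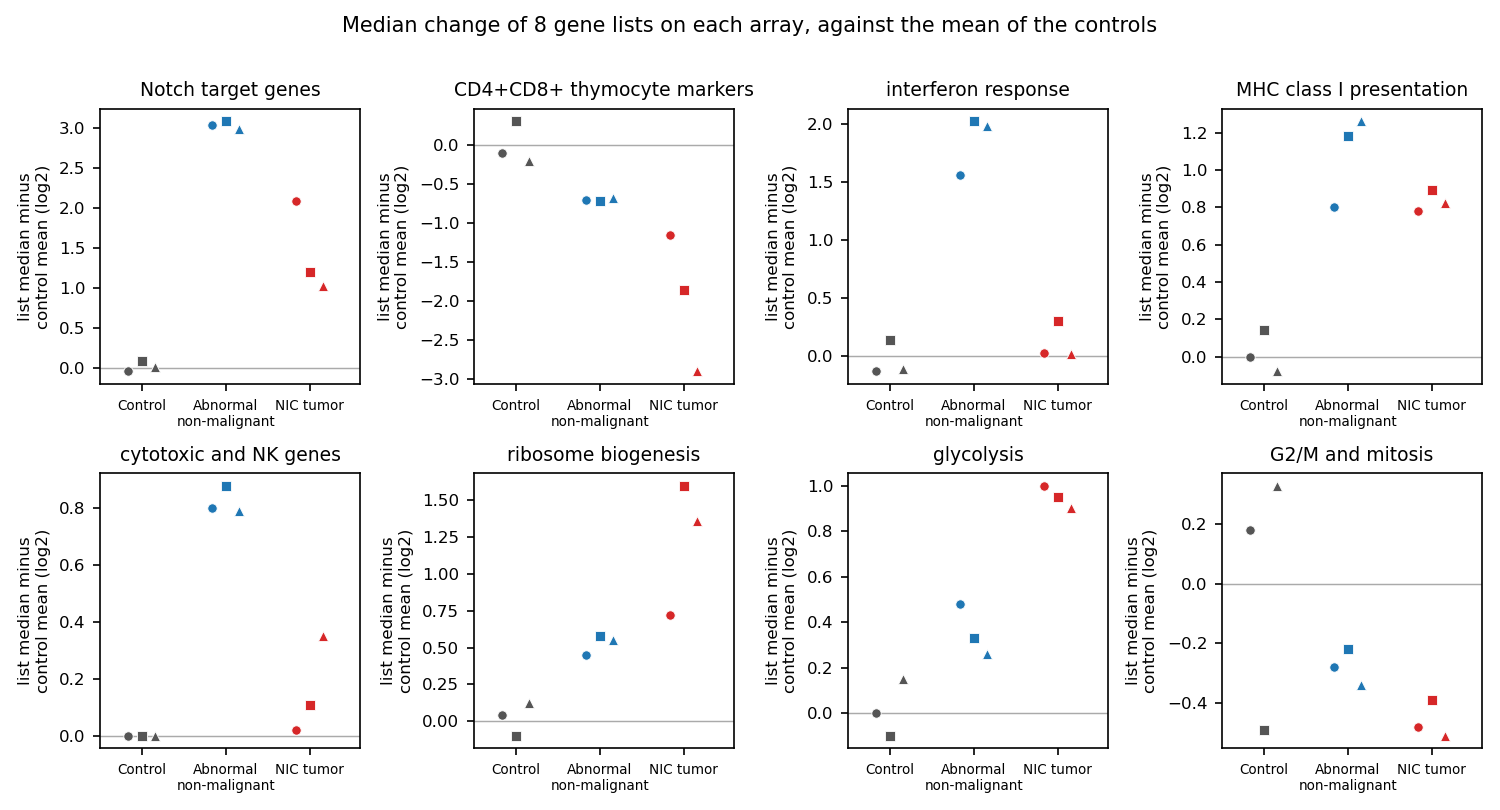
Median change of the genes of 8 lists on each array, in log2 units relative to the mean of the controls; circles, squares and triangles are arrays 1, 2 and 3 of a group, and the grey line marks 0. Interferon response genes stand at 1.56 to 2.02 on the non-malignant arrays and at 0.02 to 0.3 on the tumor arrays, and CD4+CD8+ thymocyte markers reach −2.9 on tumor array 3.

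Some markers of other cell types stood higher in the tumors, most of them in single tumors. Ctss was the exception, at 7.77, 9.18 and 8.41 on tumors 1, 2 and 3 against at most 6.33 in controls. Of 15 myeloid markers, Ctss rose by 2.51 (1 adjusted over the list alone; camera adjusted p = 0.0166, and adjusted p = 0.49 with an estimated correlation). The call of the myeloid list ended without tumor 2, whose S100a8 stood at 8.35 against 4.76 to 6.07 in controls, and without tumor 1 the markers that rose numbered 8. The erythroid marker median stood at 2.2 on tumor 2 and at 0.25 and 0.41 on tumors 1 and 3, and 0 of 7 passed by limma (4 at an unadjusted p under 0.05, 4 adjusted over the list alone). By limma, 0 of 6 antigen-presenting cell markers passed (1 at an unadjusted p under 0.05), and 0 of 8 thymic stroma markers (0). B cell markers Ighm (−0.89) and Cd79b (−1.38) fell, 2 of 10, at −1.12 to −0.67 and −1.78 to −1.05 with 1 array left out (2 fell when adjusted over the list alone). With the mean of its probe sets Ighm stood at 0.1, in the other direction. Both calls ended without any 1 control, non-malignant 2, non-malignant 3 or tumor 2, that of Ighm also without tumor 3 and that of Cd79b also without tumor 1. Early thymocyte progenitor markers had a median of 0.3 with 2 of 13 called, Il2ra (5.61) and Lyl1 (2 adjusted over the list alone; camera adjusted p = 0.0462, and adjusted p = 0.381 with an estimated correlation). The list call did not hold without control 1, control 3 or tumor 3. The call of Lyl1 (0.64, between 0.49 and 0.83 with 1 array left out) ended without any 1 array except tumor 1.

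Among stress and survival genes, the p53 target list was lower in the tumors (median −0.67, camera adjusted p = 0.00776, and adjusted p = 0.335 with an estimated correlation). The list median lay at −0.31 and −0.41 on tumors 1 and 2 and at −1.19 on tumor 3, without which the median log2 fold change was −0.46 and the list was still called. Of its 16 genes 1 was called, the death receptor gene Fas (−2.01), while 6 fell and 1 rose when adjusted over the list alone. Tcf4, an E protein gene, fell by 1.82, and with Id1 (1.85) and Lyl1 it made 3 of 8 called in its list (the same adjusted over the list alone), the call of Lyl1 (0.64) resting on single arrays as above. In the BCL2 family 2 of 11 fell (4 fell and 1 rose when adjusted over the list alone), Bcl2l1 (−2.01) and Mcl1 (−0.96), the latter losing its call without any 1 control or tumor 2, at −1.22 to −0.74. Of 10 NF-kappaB response genes, Tnfaip3 (−1.7) and Nfkbia (−0.73) fell and Bcl3 (0.93) rose (6 fell and 2 rose when adjusted over the list alone); without control 2, control 3 or tumor 2 Nfkbia was not called (−0.91 to −0.61), nor was Bcl3 without any 1 control, non-malignant 2 or tumor 3 (0.7 to 1.08 over the 9 fits). Xbp1, a regulator of the unfolded protein response, fell by 2.2, and 2 of the 12 genes of that list fell and 2 rose (2 and 3 adjusted over the list alone). The list's median was 0.1 and its mean −0.13. Of 8 heat shock genes Dnajb1 fell by 0.84 (1 adjusted over the list alone; −0.92 to −0.76 with 1 array left out, its call ending without any 1 control or tumor 2). Of 12 immediate early genes Fosb (1.54) rose and Jund (−1.02) fell (1 and 2 adjusted over the list alone; median 0.43, mean 0.04, test pointing down). The call of Fosb ended without control 1, control 3 or tumor 3 (1.24 to 1.72 over the 9 fits), and that of Jund without any 1 control, any 1 non-malignant array or tumor 3 (−1.31 to −0.67). Of 17 T-ALL driver genes 2 rose and 3 fell (2 and 4 adjusted over the list alone; median 0.2, mean −0.1), among them Bcl11b (−1.68) and Lef1 (0.82), whose calls ended without control 2, control 3 or tumor 2, at −2.14 to −1.24 and 0.69 to 1.06 over the 9 fits. Of 8 housekeeping genes Pgk1 (0.46) and B2m (1.13) rose (2 adjusted over the list alone), Pgk1 not without control 1, control 2 or tumor 2 (0.41 to 0.51) and B2m not without control 1 or 3 (0.87 to 1.37). Of 16 study genes 3 rose, Myc, Hes1 and Dtx1, and 5 fell, Rag1, Rag2, Mdm4 (−1.52), Cd4 (−2.12) and Cd8b1 (−1.7), against 3 and 7 adjusted over the list alone. Mdm4 lost its call without control 2 (range −1.82 to −1.2), as Cd4 and Cd8b1 did without any 1 control (−2.6 to −1.5 and −2.01 to −1.1). Besides Notch1, the study genes that did not pass were Cd8a (−1.42), Id3 (−1.11), Mdm2 (−0.75), Ptcra (−0.57), Tcf12 (−0.34), Cdkn2b (−0.08) and Tcf3 (0.44). Without tumor 1 the genes that fell numbered 7 on the p53 target list, 5 in the BCL2 family, 5 among T-ALL drivers and 9 among study genes. Without control 2 or 3 no T-ALL driver gene was called (0), and without control 1, 2 or 3 the study genes that fell numbered 3, 2 and 3. In the stress response list 1 fell without any 1 control or tumor 2.

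The 8 largest rises in the tumors had log2 fold changes from 4.62 to 6.72, namely Dsp (6.72), Il2ra, Epas1 (5.41), Adam19 (5.02), Plac8 (4.9), Dtx1, Mycn (4.72) and Heyl. The 8 largest falls were Bex1 (−5.15), Dntt (−4.91), the enzyme that adds untemplated nucleotides in antigen receptor genes, Ccr9, Fgf13 (−4.49), Rag1, Glcci1 (−4.19), Plxnd1 (−3.83) and Dhrs3 (−3.81). With Dsp and Epas1 under the 40th percentile on all 3 controls and Bex1 on all 3 tumors, their sizes and order are uncertain here too, and set against that level Dsp rose by at least 5.09, Epas1 by at least 4.48 and Bex1 fell by at least 3.58. Fgf13 lay under it on 2 tumors (at least 3.83 lower). Bex1 was again not tested without any 1 control and kept the call in the other 6 fits. Dntt and Glcci1 lost their calls without any 1 control or tumor 2, and Dntt also without non-malignant 2, non-malignant 3 or tumor 3, at log2 fold changes of −6.74 to −3.45 and −5.57 to −3.11. In all, limma called 2083 of 13296 genes, 1127 higher and 956 lower (566 and 624 of them at least 2-fold), against 4280 at an unadjusted p under 0.05. The groups did not overlap in 32.5% of all genes, where chance gives 10%, nor in 2070 of those called. In the simulation at the spread of tumors and controls, false calls exceeded the share that the threshold allows, so more of these calls may be false than it states. The count was 1470 with non-malignant arrays 2 and 3 averaged, 1134, 922 and 1010 without control 1, 2 or 3, 4119 without tumor 1, 1230 without tumor 2 and 841 with only these 2 groups in the fit. With the mean spike-in signal as a covariate it was 288. This signal was higher on all 3 tumors (10.54, 10.99 and 11.93) than on any other array (at most 10.44). The covariate thus stands partly for the tumor group itself, and lost calls do not tell an artifact from a group difference. The 8 largest rises kept their calls with this covariate, as did Bex1 and Dhrs3 among the falls, and 34 of all 75 called genes named here by rule.

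Both comparisons against control moved many of the same genes. Dsp, Epas1, Mycn, Il2ra, Dtx1, Heyl and Hes1 rose in both, and Bex1 and Dhrs3 fell in both. Of the 382 genes that rose in the non-malignant samples, 211 also rose in the tumors, and of the 87 that fell, 75 also fell. Lists drawn independently would share 32.4 and 6.3. The comparisons share the control arrays, which ties them together even without any effect. How far this raises the shared counts was not measured. No gene was called in opposite directions (0, with limma; 23 at an unadjusted p under 0.05 in both, against 1095 in the same direction). Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.59, against 0.5 in 20 simulations of unchanged groups on the same controls, with a covariance of 0.216 against 0.032. The simulations gave all groups the same spread per gene, whereas the real spreads were 0.27 in controls, 0.23 in non-malignant samples and 0.49 in tumors. The simulated values therefore do not set the level that shared controls give in these groups. The shared count of 286 was 128 with non-malignant arrays 2 and 3 averaged, 172, 162 and 161 without control 1, 2 or 3, and 128 and 135 without non-malignant 2 or 3.

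**Figure D3:**
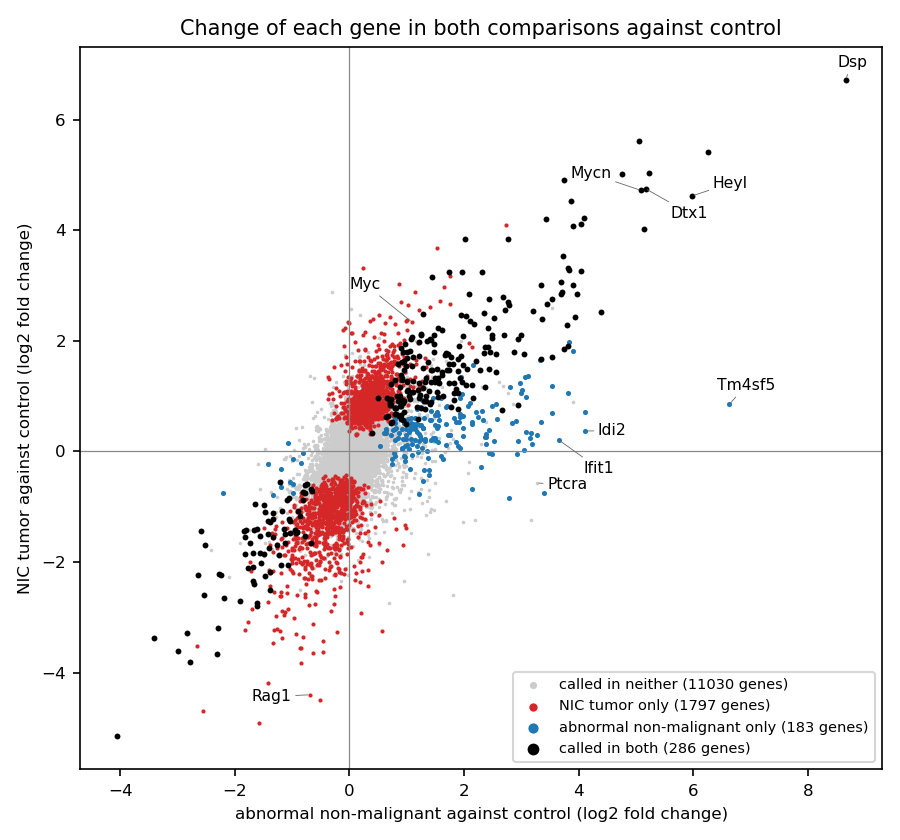
Log2 fold change against control of each of 13296 genes in abnormal non-malignant samples (horizontal axis) and in NIC tumors (vertical axis); black points are the 286 genes called in both comparisons, colored points those called in 1, and grey points the rest. Dsp lies highest in both, at 8.66 and 6.72, and Tm4sf5 is high in non-malignant samples alone, at 6.63 against 0.85.

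The comparison of NIC tumors with abnormal non-malignant samples asks what separates the malignant from the non-malignant state, and also tests whether the changes against control differ in size. Some genes were high in the non-malignant samples and near the control level in the tumors. Tm4sf5 stood at 5.25 ± 0.13 in controls, 11.88 ± 0.13 in non-malignant samples and 6.11 ± 0.74 in tumors (log2, mean ± SD, n = 3 each). The Notch target Hey1 followed the same course at 6.39 ± 0.22, 10.5 ± 0.8 and 7.1 ± 0.1, a fall by 3.41 in the tumors (adjusted p = 0.00203). Of the 382 genes higher in non-malignant samples than in controls, 103 were lower again in the tumors, 13 were higher still and 266 did not differ by the test. With non-malignant arrays 2 and 3 averaged these counts were 28, 0 and 150 of 178, and without array 2 or 3 the first was 28 and 27. The non-malignant arrays enter both comparisons behind these counts, with opposite signs. Values high by chance there make a fall in the tumors likelier than a further rise. How far this shaped the counts was not measured. Of 12 interferon response genes 8 fell and none rose (9 fell when adjusted over the list alone; median −1.62, camera adjusted p = 6.67e-10, and adjusted p = 0.114 with an estimated correlation). Examples were Usp18 at −3.61, Ifit1 at −3.45 (at least 3.24 and 3.13 lower with the 2 and 1 tumor arrays under the 40th percentile set to it) and the interferon-inducible gene Ifi27l2a, outside the list, at −4.16. These calls were kept with non-malignant arrays 2 and 3 averaged, where 2 of the 12 list genes fell, as without array 2 or array 3, whereas that of Irf9 (−2.26, range −2.67 to −2.04) ended without non-malignant 2 or 3.

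Thymocyte and growth genes also separated these groups. Rag2 fell by 3.05 and Xbp1 fell by 2.31, and the glycolytic enzyme gene Pkm rose by 1.09; all 3 kept the call with non-malignant arrays 2 and 3 averaged, although Pkm lost it without array 3 (range 0.96 to 1.21). Of 11 CD4+CD8+ thymocyte markers 2, Rag1 and Rag2, fell (9 fell when adjusted over the list alone; camera adjusted p = 1.06e-05, and adjusted p = 0.303 with an estimated correlation). Of 13 TCR and CD3 signalling genes 2 fell and 1 rose (6 and 1 adjusted over the list alone; camera adjusted p = 0.000335, and adjusted p = 0.354 with an estimated correlation). Of 10 cytotoxic and NK genes 3 fell (4 fell and 1 rose when adjusted over the list alone; camera adjusted p = 0.0193, and adjusted p = 0.235 with an estimated correlation). Among these, Nkg7 fell by 1.64. The list call did not hold without tumor 1 or tumor 2. Of 12 Notch target genes 2, Hey1 and Ptcra (−3.84), fell (5 fell when adjusted over the list alone; camera adjusted p = 0.0193, and adjusted p = 0.38 with an estimated correlation). Its call ended without tumor 2. Of 21 ribosome biogenesis genes 5 rose (15 adjusted over the list alone; camera adjusted p = 5.68e-08, and adjusted p = 0.314 with an estimated correlation). Of 17 Myc target genes 2 rose (5 adjusted over the list alone; camera adjusted p = 0.000613, and adjusted p = 0.368 with an estimated correlation). Of 12 glycolysis genes 4 rose (7 adjusted over the list alone; camera adjusted p = 0.0025, and adjusted p = 0.271 with an estimated correlation). Of 19 oxidative phosphorylation genes 0 passed by limma (4 at an unadjusted p under 0.05; camera adjusted p = 0.00966, and adjusted p = 0.314 with an estimated correlation). Both list calls ended without tumor 1. NF-kappaB response genes were lower as a list with 0 of 10 called by limma (6 at an unadjusted p under 0.05, 5 adjusted over the list alone; camera adjusted p = 0.00559, and adjusted p = 0.172 with an estimated correlation). G2/M and mitosis genes were lower with 1 of 19 called, Top2a (2 adjusted over the list alone; camera adjusted p = 0.0494, and adjusted p = 0.726 with an estimated correlation). The list call did not hold without control 1, non-malignant 1, non-malignant 2, tumor 1 or tumor 2, and by fry the list did not pass (adjusted p = 0.426). The calls of Rag1, Ptcra and Top2a (−0.67) ended without control 1, control 3, any 1 non-malignant array, tumor 2 or tumor 3, that of Rag1 also without control 2. Their ranges with 1 array left out were −5.04 to −2.97, −4.97 to −3.02 and −0.72 to −0.64. Without any 1 non-malignant array, or with arrays 2 and 3 averaged, 0 genes of the Myc target, ribosome biogenesis and TCR and CD3 signalling lists were called and 1 cytotoxic and NK gene, Nkg7. Of the glycolysis genes 1 was called in these fits, or 0 without array 3. The 5 lists were themselves called in each of them.

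The other lists did not pass by camera between tumors and non-malignant samples. Few of their genes were called, among p53 target genes (Pmaip1, which lay under the 40th percentile on all 3 tumors and fell by at least 1.35 against that level, and Fas at −1.21, 2 of 16, and 2 adjusted over the list alone), E proteins, Id proteins and partners (Id1 at −1.89 and Tcf4 at −1.28, 2 of 8, and 2), mature T cell markers (Ltb at −1.81, 1 of 14, and 4 lower and 1 higher), B cell markers (Cd22 at −1.56, 1 of 10, and 2) and G1/S genes (Ccne2 at −2.21, at least 1.47 lower with 2 such tumor arrays, 1 of 18, and 2 lower and 2 higher). Adjusted over the list alone, the like counts followed for immediate early genes (Jun at −2.22 and Egr2 at −1.39, 2 of 12, and 2), heat shock genes (Hspa1b at −4.4 and Hsph1 at −1.38, 2 of 8, and 4 lower and 1 higher), the unfolded protein and amino acid stress response (Xbp1 at −2.31 and Pdia4 at 1.14, 2 of 12, and 2) and the BCL2 family (Pmaip1, 1 of 11, and 3 lower). Median and mean differed in sign for the B cell markers (0.11 and −0.2), the G1/S genes (0.03 and −0.05), the stress response (0.15 and −0.08), the early progenitor markers (0.08 and −0.03), the myeloid markers (0.16 and −0.03), the housekeeping genes (0.08 and −0.03) and the T-ALL driver genes (0.01 and −0.19). By limma 0 of 13 early thymocyte progenitor markers passed (2 at an unadjusted p under 0.05), 0 of 15 myeloid markers (4), 0 of 6 antigen-presenting cell markers (0), 0 of 7 erythroid markers (0), 0 of 8 thymic stroma markers (1), 0 of 9 MHC class I presentation genes (4), 0 of 17 T-ALL driver genes (3) and 0 of 8 housekeeping genes (2). Adjusted over the list alone, 2 MHC class I presentation genes and 1 T-ALL driver gene fell. By fry the mature T cell and E protein lists passed in this comparison (adjusted p = 0.0388 each). Of 16 study genes Myc rose (1.25) and Ptcra, Rag1 (−3.71) and Rag2 fell (1 and 5 adjusted over the list alone). Notch1 (−2), Hes1 (−0.51), Dtx1 (−0.42), Cd4 (−1.69), Cd8a (−1.06), Cd8b1 (−1.12), Mdm2 (−0.32), Mdm4 (−1.11), Cdkn2b (0.08), Tcf3 (0.51), Tcf12 (−0.6) and Id3 (−0.41) did not pass. Of the genes named in this paragraph and called, only Rag2 and Xbp1 kept the call with non-malignant arrays 2 and 3 averaged, and the others lost it also without array 2 or array 3 alone (67 and 57 genes called in all).

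In all, limma called 562 of 13296 genes between tumors and non-malignant samples, 203 higher and 359 lower (95 and 261 of them at least 2-fold), against 3444 at an unadjusted p under 0.05. The groups did not overlap in 27.1% of all genes, where chance gives 10% for independent samples, and more if non-malignant arrays 2 and 3 are 1 sample. Among the 8 largest falls, Tm4sf5 (−5.78), Ifi27l2a and Tctex1d1 (−3.82, though not without array 3, range −4.55 to −3.2) kept the call with non-malignant arrays 2 and 3 averaged, Idi2, which lay under the 40th percentile on all 3 tumors and fell by at least 3.29 against that level, did not pass the filter on dim probe sets there, and Hspa1b, Fgf13 (−3.98, at least 3.32 lower with 2 such tumor arrays), Ptcra and Rag1 lost the call. None of the 8 largest rises kept it (Susd4 at 2.37, Chchd10 at 2.33, Ccdc18 at 2.31, Prmt7 at 2.15, Chd7 at 2.12, Fbln1 at 2.1, Sbf2 at 2 and Rangrf at 1.98). Without tumor 1 or tumor 3 another probe set of Fbln1 had the highest mean and gave −0.18 and −0.24, while the usual probe set gave 1.66 and 2.09. The count was 66 with those arrays averaged, 170, 67 and 57 without non-malignant 1, 2 or 3, 214 and 204 without control 1 or 3, and 3408, 225 and 324 without tumor 1, 2 or 3. It was 110 with only these 2 groups in the fit. With the spike-in signal as a covariate it was 11, with Tm4sf5, Ifi27l2a and Idi2 among those called, and with the B1 repeat signal it was 94. The spike-in signal was higher on every tumor than on every non-malignant array, so its covariate stands partly for the group itself.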

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

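Of the tests reported in this part, those of the interferon response, of dilution and of the CD3 genes, and the splits of the arrays by gene counts, were chosen after the results were seen. On tumor array 3 the bioB spike-in read 10.67, above the highest control array at 8.28. The 18S ribosomal RNA probe sets read 10.7 on non-malignant array 3 and 10.94 on tumor array 3, against at most 8.02 in controls. Of 4753 probe sets without a gene of their own, which no comparison of genes used, 82 were called higher in tumors than in controls and 23 in non-malignant samples than in controls (202 and 15 were called lower).

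Interferon response genes stood higher on the non-malignant arrays than on all others. A single sample measured on both arrays 2 and 3 is argued against as the whole source, since array 1 alone lay 1.42 above the highest control and 1.27 above the highest tumor array (log2 list median). For a batch seen by the B1 repeat signal, the non-malignant arrays stood above the others among the 5 arrays of high signal (gap 1.27) and among the 4 of low signal (gap 1.84). As every non-malignant array stood above all other arrays, this outcome was fixed by the pattern and is no further evidence. The signal itself was high and low both among controls and among non-malignant arrays, so it did not separate these groups. The explanation by a mix of myeloid and antigen-presenting cells was narrowed, after its result was seen, to a mix that raises all their markers alike. These markers changed by a median of 0.22 against 1.9 for the interferon list (difference 1.67, 95% bootstrap interval over genes, which are not independent, 0.63 to 2.36). Lyz2 stood at 0.07 and Cd74 at 0.05, but S100a8 at 2.76, S100a9 at 2.61 and Ctss at 2.34. The last 3 genes already went against the narrowed form, so the test does not decide on a mix of such cells. Ngp (0.99), Ltf (0.68), Mpo (0.34) and Camp (0.29) also stood higher on every non-malignant array than on every control, while Elane differed by 0.05. Tumor array 2 had S100a8 at 8.35, S100a9 at 8.28 and Ctss at 9.18, against at most 8.03, 7.57 and 8.65 on the non-malignant arrays. Its interferon list median was 0.3, which is a single array. A share of granulocytes or other cells rich in such genes stays open, as do a response to interferon in the cells themselves, a shift between T cell subsets and cytotoxic cells of another kind, all of them untested.

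CD4+CD8+ thymocyte markers stood lower on the tumor arrays than on the controls. Dilution by cells outside the T lineage would lower the shared CD3 genes as far, but the median of Cd3e, Cd3d and Cd3g lay above the marker median by 1.13, 1.46 and 2.34 on tumor arrays 1, 2 and 3. Cd247, the CD3 zeta chain, was not part of this test and fell by 2.09 (9.16 to 10.72 on the tumor arrays, against a mean of 11.89 in controls). Dilution as the whole source is thus argued against by Cd3e, Cd3d and Cd3g only. A compressed signal of bright probe sets would lower other genes of the same brightness, but in each tumor array the marker median lay below all 10000 matched random lists (highest percentile 0), whose medians were −0.04, −0.15 and −0.29. A block or shift in the stage of the tumor cells may account for the change, as a hypothesis with no test of its own beyond these.

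The tumor arrays spread along the first principal component, which held 46.9% of the variance, with scores of 1, 72.1 and 129.9 for arrays 1, 2 and 3. Compression of the signal on array 3 is argued against as the whole source, since its genes differed from those of array 1 with an SD of 0.79 and still 0.76 after a trend on brightness was removed, against at most 0.41 between controls. Different shares of cells outside the T lineage stay open: the CD3 gene median ranged over 0.53 between the tumor arrays, between the bounds set for either answer. Differences between the tumors themselves stay open as well and were not tested.

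The 6 arrays of a comparison allow 10 splits into 3 and 3, too few for a share under 0.05. The real split, 1 of the 10, called 2083, 469 and 562 genes for tumors against controls, non-malignant samples against controls and tumors against non-malignant samples, and the highest other split called 1, 0 and 0. For gene lists, adjusted over the 27 lists of a comparison with the third group kept in the fit, the real splits called 12, 13 and 10 lists and the highest other splits 11, 10 and 8.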

How the results depend on the processing

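The alternatives that averaged non-malignant arrays 2 and 3, used the spike-in or B1 repeat signal as a covariate, or weighted the groups were chosen after seeing the data. Both scalings, both filters, all probe sets or their mean, and variance without trend or with robust estimation kept the number of genes called within 1.5 times in the 3 comparisons, at 1797 to 2305, 438 to 478 and 540 to 684 or, without a filter, with all probe sets or with their mean, 381 to 467. The shared genes numbered 252 to 296 there. With 1 array left out, tumors against controls gave 922 to 4119 genes, non-malignant samples against controls 203 to 709, tumors against non-malignant samples 57 to 3408, the shared genes 128 to 413 and the list calls 31 to 38 (36 with all arrays, 31 to 44 over the settings with a preset correlation). With an estimated correlation limma's camera left 0 of 81 list calls (14 at an unadjusted p under 0.05). By fry the lists that passed differed in part (its adjusted p in parentheses). In non-malignant samples against controls, ribosome biogenesis (0.0784), myeloid (0.162), CD4+CD8+ thymocyte (0.222) and G2/M lists (0.346) did not pass. In tumors against controls, TCR and CD3 signalling (0.0971), myeloid and G2/M lists (0.0811 each) did not. Cytotoxic (0.00365), mature T cell (0.00499) and NF-kappaB lists (0.00102) passed there. A floor on low values, planned for a linear table, was not run. An adjusted p under 0.01 left 584, 233, 83 and 115 (in the same order, shared genes last), and a change of at least 2-fold left 1190 tumor and 356 tumor against non-malignant genes, as stricter thresholds must. Array weights gave 4885, 2421, 5700 and 1334, and weights per group 1340, 1282, 283 and 503. Only the 2 groups in the fit gave 841, 1119 and 110. Fewer arrays then stand behind each variance, which also leaves out the spread of the third group (0.49 in tumors, 0.27 in controls and 0.23 in non-malignant samples). The rise from 469 to 1119 came with the tumors left out. Weights per group moved the 3 counts in the same directions. The replicate block gave 287 for tumors against non-malignant samples. Non-malignant arrays 2 and 3 as 1 gave 206, 66 and 128 for non-malignant samples against controls, tumors against non-malignant samples and the shared genes. The spike-in covariate gave 288, 11 and 178 for the tumor comparisons and the shared genes, and the B1 repeat covariate 94 for tumors against non-malignant samples. As the spike-in signal was higher on every tumor than on all other arrays, its covariate takes up part of the group difference. Except where stated, the cause was not tested.

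Some named log2 fold changes reversed, nearly all of them small or not called. Xist, between tumors and non-malignant samples, was −0.01 with quantile scaling, −0.54 with all probe sets, −0.24 with their mean and also without tumor 1, −0.15 without non-malignant 2, −0.06 without non-malignant 3, −0.1 with these 2 as 1, −0.58 with the spike-in covariate and −0.5 with the B1 repeat covariate (−0.24 to 0.23 with 1 array left out). Without control 2 it was −0.3 in tumors (up to 1.21 with another array left out) and −0.31 in non-malignant samples against controls (up to 1.2). Against controls in non-malignant samples, Tcf12 was −0.8 with all probe sets and −0.21 with their mean, Rag2 0.07 without control 2, Cd8a 0.01 without non-malignant 1 (lowest −0.57) and Siglech 0.01 without non-malignant 3. In tumors against controls, Ighm, which was called, was 0.1 with the mean of probe sets, Notch1 −0.56 with array weights and −0.14 without tumor 1 (highest 1.82), and Ptcra 0.25 without tumor 3 (lowest −1.7). Between tumors and non-malignant samples, Ighm was 0.14 and Tap1 0.06 with the mean of probe sets, Id3 0.74 with array weights and 0.08 without tumor 3 (lowest −1.12), Cdkn2b −0.01 without non-malignant 1 (highest 0.15), and Fbln1, which was called, −0.18 without tumor 1 and −0.24 without tumor 3 (highest 2.54), where another of its probe sets had the highest mean and the usual one gave 1.66 and 2.09. With the spike-in covariate, tumors against controls gave Itgax −0.2, H2-Aa −0.39, Usp18 0.09, Cdkn2b 0.05, Tcf12 0.22 and Ptcra 1.05, and tumors against non-malignant samples gave Siglech −0.25, H2-Aa −0.53, Dnajb9 0.17, Mdm2 0.26, Tcf12 0.02, Cd8a 0.41, Cd8b1 0.16 and the antigen-presenting cell markers a median of −0.37, a list call not made otherwise in this comparison. Except for Fbln1, the cause was not tested. Quantile scaling moved the median of all genes in tumors against controls to 0.11, from 0.064. Signal over background limits the dim genes. Besides the genes given with a bound, some arrays of the dimmer group lay under the filter for other named and called genes, whose bounds lay at most 0.3 under the value. Genes that were not called received no bound. Among them, S100a9 lay at 4.3 and 4.74 on controls 2 and 3, under the filter at 5.22 and 5.2. Cdkn2a lay under the filter with 4.34 to 5.14 on all arrays. Its tumor values (4.85 to 5.14) lay above all others (at most 4.78), and in the fit without a filter it did not pass (log2 fold change 0.42 against controls, adjusted p = 0.119, and 0.41 against non-malignant samples, adjusted p = 0.163).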

Other observations

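The gene families in this part, 12 in each of the 3 comparisons, were chosen after the data were seen, as were all their tests, and no call among them held with an estimated correlation. In tumors against controls, families of protein synthesis and folding, and the protein arginine methyltransferases, were higher beyond the genes of the fixed lists. Of 76 mitochondrial ribosomal proteins 24 rose and none fell (median log2 fold change 0.51, camera adjusted p = 1.79e-09, and adjusted p = 0.258 with an estimated correlation). Of 32 aminoacyl-tRNA synthetases 14 rose (median 0.67, adjusted p = 2.8e-06, and adjusted p = 0.224 with an estimated correlation), among them Vars (1.6), Nars2 (1.31) and Gars (0.97). Of 7 protein arginine methyltransferases 5 rose (median 1.38, adjusted p = 0.00211, and adjusted p = 0.14 with an estimated correlation), with Prmt7 at 3.68, Prmt1 at 1.69 and Prmt5 at 1.46. Of 8 subunits of the CCT chaperonin, which folds actin and tubulin, 5 rose (median 0.44, adjusted p = 0.000522, and adjusted p = 0.147 with an estimated correlation). Cytosolic ribosomal proteins moved less, with 11 of 42 called higher (median 0.2, adjusted p = 2.29e-05, and adjusted p = 0.147 with an estimated correlation). The directions held under quantile and median scaling.

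Guanylate-binding proteins, which interferon induces, fell together in tumors against non-malignant samples, 6 of 6 (median −2.65, camera adjusted p = 4.4e-07, and adjusted p = 0.14 with an estimated correlation), and 2 of 6, Gbp3 (2.48) and Gbp2b (2.13), rose in non-malignant samples against controls (median 1.91, adjusted p = 0.000591, and adjusted p = 0.243 with an estimated correlation). Against controls the tumors had 2 of 6 lower, Gbp8 (−3.56) and Gbp7 (−2), and the family lower (median −1.07, adjusted p = 0.0111, and adjusted p = 0.308 with an estimated correlation). Histones were lower in non-malignant samples than in controls, with 2 of 14 called (median −0.47, adjusted p = 2.1e-05, and adjusted p = 0.117 with an estimated correlation), and in tumors than in controls, with 3 of 14 (median −0.32, adjusted p = 0.00448, and adjusted p = 0.14 with an estimated correlation). These directions held under both scalings as well. Counting all called genes, 103 stood higher in non-malignant samples than in both other groups, 7 of them on the interferon list, and 4 stood lower than in both. The tumors stood above both other groups in 188 genes and below both in 179. With non-malignant arrays 2 and 3 averaged these counts were 28 (2 on the interferon list), 0, 11 and 26. With 1 array left out they ranged over 27 to 240, 0 to 17, 6 to 1301 and 23 to 1308, highest without tumor 1. Each pattern uses the arrays of 1 group in 2 comparisons, which ties these together even without any effect.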
